A study of Homo sapiens with 6 samples.

How the data were processed

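RNA was sequenced from 6 cultures of RBE cells, 3 transfected with a control siRNA and 3 with siRNA against CHAF1A, with reads of 150 bp. The values used are gene-level read counts that the authors deposited as 1 table of whole numbers, with no normalisation. The submitters' processing notes name the read trimmer fastp 0.20.1, the aligner HISAT2 2.1.0, SAMtools 1.9, the read counter featureCounts 2.0.1, StringTie 2.1.4 and the genome build hg38, without giving their settings or the role each had. The annotation release, the treatment of reads that map to several places and the strand setting of the counting are not given in the sources used here. The design text describes strand-specific libraries. Reads of overlapping or antisense genes, and of near-identical copies such as histone genes, are therefore uncertain in their assignment. Counts of transposable elements were not analysed here.

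The 6 columns of the table carry the short names NC and si with the numbers 1 to 3. NC was read as negative control, and each column was matched to the title with the same group and number. That reading is not stated in the labels. The level of CHAF1A in each library, given first in the results, bears on it. No column of other samples was present (0). The labels do not say whether 1 or several siRNAs were used, nor their sequences. The design text calls the 3 samples of a group biological replicates and says nothing more of how they were made, so the p-values measure the spread between these 6 samples. No replicate pair was a duplicate: a chi-square per degree of freedom over genes with at least 20 counts in a pair lay between 2.30 and 13.7 within groups.

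The table holds 63186 Ensembl gene identifiers, of which 27527 had no count in any of the 6 libraries. A symbol was given to 62665 through a gene name table, and 58173 were found in GENCODE 29, which supplied positions (GRCh38, the assembly also called hg38), gene types and 3' UTR sequences. No row lacked a gene name (0). Totals per library ran from 15643381 to 20918997 counts. Genes were kept by edgeR's filterByExpr with a minimum count of 10 and a minimum total of 15, which left 15911.

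Differences between the groups were tested with edgeR 4.0.16 in R 4.3.3, by the robust quasi-likelihood test on the deposited counts with TMM normalisation and no further covariate, and p-values were adjusted by the Benjamini-Hochberg method over the 15911 genes at a threshold of 0.05. "Higher" and "lower" mean past that threshold in si-CHAF1A against si-Ctrl. Levels are CPM, counts scaled to a common library size with the TMM factors, computed here from the deposited counts, as mean ± SD over n = 3 libraries per group. A log2 fold change is the fitted value of si-CHAF1A over si-Ctrl, and SE is its size divided by the square root of the test's F value. The common dispersion corresponded to a biological coefficient of variation of 8.12%.

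Gene lists (30) were written before the data were examined. They were tested with camera in limma 3.58.1 on log2 CPM (prior count 2), two-sided, with a preset correlation of 0.01 between genes and adjustment over the 28 lists with at least 5 tested members. The same test was run with the correlation estimated from the data, which gave 0 calls (6 lists at an unadjusted p under 0.05), and fry was run as a further description. For each list the number of members past the test over all genes is given with the number when p-values are adjusted over the list alone.

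Genes were named by a rule set before the data were examined. The rule takes CHAF1A, CHAF1B, NAT10 and the histone chaperones past the test. It takes the 10 largest rises and the 10 largest falls among genes with a symbol, an adjusted p under 0.05, a mean log2 CPM of at least 2 and no overlap between the groups. It takes up to 4 members of each list with the smallest adjusted p, and the 5 genes with the smallest p overall. Some genes that the rule takes are not reported here. Members named beyond the rule are marked as chosen after their values were seen.

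To see whether siRNA sequence effects could be measured, all 16384 words of 7 bases were scanned in the 3' UTRs of 11267 genes with a 3' UTR of at least 50 bp and a mean log2 CPM of at least 1. The fold change (limited to 2 on the log2 scale either way) was regressed on the presence of a word, with 3' UTR length, GC content and mean level as covariates. The words were chosen on a random 5633 of the genes and tested on the other 5634. A scan over all genes had been looked at before this split was set up, so the held-out genes were not untouched. Where list members are divided into those with and without any of the words, words of lower and of higher genes are pooled. They are sought in the whole transcript, so this division has no direction and is not adjusted for transcript length. Only 1 coding transcript per gene, the one with the longest coding part, was searched in the scan and in this division. A word present only in another transcript of a gene was not counted.

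The gene test, the list test with the preset correlation and the word scan were tried on simulated data. The other tests were not. In 3 simulations of 15911 genes with the means, library sizes and dispersions of this comparison and 200 changed genes each, the test recovered 18.7% of genes changed 1.25-fold, 58% at 1.5-fold, 82% at 2-fold and 98% at 4-fold, and called 32 of 47133 unchanged genes. The adjusted threshold depends on the share of changed genes, and 6008 genes were called in the data. These recovery rates therefore need not hold there. The list test called 0 of 60 unchanged lists and 30 of 30 lists of 30 genes shifted 1.25-fold. The simulated genes were drawn independently, whereas the correlation estimated in the data was 0.171 for mitosis genes and 0.534 for ribosomal proteins. The simulation therefore does not measure false calls among lists of correlated genes. The word scan recovered 3 of 3 planted words.

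Alternatives covered DESeq2 1.42.0 and limma-voom, other scalings, other filters on low counts, a replicate block, leaving out each library in turn, a minimum fold change, a test against a 1.2-fold change, and other list tests. Added after seeing the data were the restriction to genes without the words, scaling by abundant genes, thinning to the smallest total, a fit without robust dispersion, and the gene families of the closing section. Python 3.11.15 with NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 was used for sequences and plots.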

Results

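Gene-level read counts were obtained for 6 libraries of RBE cells, an established line of human intrahepatic cholangiocarcinoma, a cancer of the bile ducts within the liver. Cells at about 60% confluency were transfected with a control siRNA (si-Ctrl, 3 libraries) or with siRNA against CHAF1A (si-CHAF1A, 3 libraries), given fresh medium after 24 h and harvested at 48 h. CHAF1A is the large subunit of chromatin assembly factor 1 (CAF-1), which places histones on newly replicated DNA. The series deals with the RNA acetyltransferase NAT10, chromatin and the silencing of transposable elements in this cancer, and this comparison asks which transcripts change when CHAF1A is reduced. The libraries held 15643381, 20918997 and 17479039 counts in si-Ctrl 1, 2 and 3, and 16564712, 17112144 and 17601483 counts in si-CHAF1A 1, 2 and 3. The first principal component carried 65.1% of the variance and separated the groups. On the second (11.2%), si-Ctrl 2 scored -29.6, away from the other controls at 14.9 and 13.9.

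CHAF1A (ENSG00000167670, chromosome 19, 4402662 to 4445018) stood at 51.5, 59.8 and 51.0 CPM in the 3 si-Ctrl libraries and at 11.1, 12.9 and 11.2 CPM in the 3 si-CHAF1A libraries. It fell 4.61-fold, from 54.1 ± 4.92 to 11.7 ± 1.03 CPM (SD, n = 3 each; log2 fold change -2.21, SE 0.10, edgeR adjusted p = 2.57e-10). Of the tested mitosis genes 42 of 44 were lower, as were 28 of 46 DNA replication genes and 32 of 46 ribosomal protein genes (20 without si-CHAF1A 2). Among replication-dependent histone genes 10 of 13 were higher, among p53 targets 21 of 32 (3 lower), and among genes of NF-kB and inflammatory cytokines 14 of 24 (4 lower). These 6 lists passed camera with a preset correlation, and none passed with an estimated one (adjusted p from 0.0701 to 0.362). DHRS2, the gene with the smallest p, rose from 4.12 ± 0.0536 to 516 ± 7.58 CPM. In all, 2944 of 15911 genes were higher and 3064 lower by edgeR's quasi-likelihood test, and 667 of the higher and 232 of the lower genes changed at least 2-fold. At 48.2% of tested genes the 3 libraries of one group all lay above those of the other, where chance gives 10%.

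Of the other CAF-1 subunits, CHAF1B was at 27.4 ± 0.452 CPM in control and 24.7 ± 1.86 CPM in knockdown cells, with each knockdown library under each control library, a difference that did not pass the test (log2 fold change -0.15, edgeR adjusted p = 0.215), and RBBP4 rose slightly (0.24). Among other histone chaperones, HJURP, which brings CENP-A to centromeres, fell 2.66-fold, from 91.8 ± 4.74 to 34.5 ± 2.80 CPM (log2 fold change -1.41, SE 0.08, edgeR adjusted p = 2.54e-09). Both subunits of FACT, the chaperone that travels with polymerases, fell, SUPT16H by 0.74 and SSRP1 by 0.39 on the log2 scale. UBN1 of the HIRA complex fell by 0.75, while its partner CABIN1 rose by 0.50. ASF1B fell by 0.35, HAT1 fell by 0.30 and NAP1L1 rose by 0.27 on the same scale. Of the 17 tested members of this list 3 were higher and 7 lower (3 and 8 adjusted over the list alone), and the list as a whole did not pass (camera adjusted p = 0.0568, and adjusted p = 0.268 with an estimated correlation). NAT10 itself fell 1.39-fold, from 83.7 ± 4.95 to 60.2 ± 1.35 CPM (log2 fold change -0.48, SE 0.07, edgeR adjusted p = 7.08e-05). A 7-base word that was more frequent in lower genes, described with the largest falls, is in the 3' UTRs of NAT10, SUPT16H and UBN1, and also in those of CHAF1B, RBBP4 and NAP1L1.

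**Figure D1:**
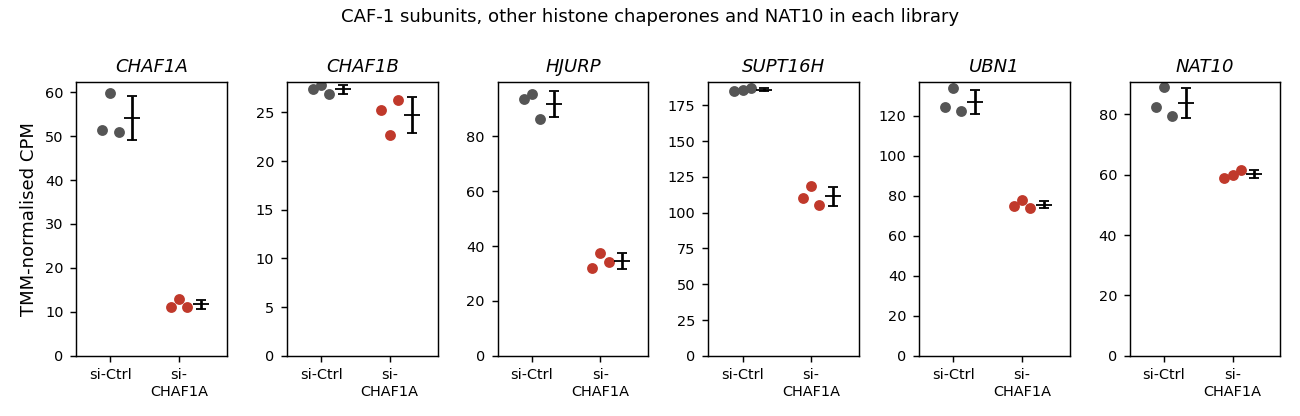
TMM-normalised CPM of CHAF1A, CHAF1B, HJURP, SUPT16H, UBN1 and NAT10 in each of the 3 si-Ctrl (grey) and 3 si-CHAF1A (red) libraries, with the mean ± SD beside the points. CHAF1A lies between 51.0 and 59.8 CPM in control and between 11.1 and 12.9 CPM in knockdown libraries.

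Among genes with a symbol and a mean log2 CPM of at least 2, the 10 largest rises were in genes at about 0.15 to 4.12 CPM in control cells. DHRS2 (ENSG00000100867, chromosome 14, 23630115 to 23645639), a short-chain dehydrogenase/reductase, rose 125-fold (log2 fold change 6.96, SE 0.08, edgeR adjusted p = 1.07e-17). DNAH3 (chromosome 16, 20933111 to 21159441), an axonemal dynein heavy chain, rose from 0.992 ± 0.207 to 109 ± 4.11 CPM (log2 fold change 6.75, SE 0.12, edgeR adjusted p = 1.83e-15). The non-coding gene LINC01554 (chromosome 5, 95852232 to 95860133) rose by 7.23 on the log2 scale and LINC02972 (chromosome 12, 8788257 to 8795789) by 6.29. The pseudogene CEACAM22P rose by 5.69, and these last 3 folds rest on 8, 9 and 10 control counts summed over 3 libraries. ACSBG1, an acyl-CoA synthetase (chromosome 15, 78167468 to 78245688), rose by 5.60. The bone morphogenetic protein co-receptor RGMA rose by 4.99, the ETS transcription factor ETV7 by 4.32 and the axonal motor KIF1A by 3.90. These folds depend on single control libraries, since ETV7 stood at 5.27 without si-Ctrl 3, KIF1A at 4.62 without si-Ctrl 2 and LINC02972 at 6.92 without si-Ctrl 1. TM4SF18-AS1 rose by 5.55 while TM4SF18 on the opposite strand fell by 0.32. Among the 5 genes with the smallest p-values are 2 that carry no symbol. ENSG00000287064 rose from 0.475 ± 0.119 to 161 ± 8.47 CPM and ENSG00000289688 from 0.403 ± 0.161 to 67.2 ± 3.11 CPM.

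With the same limits, the 10 largest falls were in genes at 6.46 to 299 CPM in control cells. MCFD2 (ENSG00000180398, chromosome 2, 46901870 to 46941855), part of a cargo receptor for export from the endoplasmic reticulum, fell 5.01-fold from 299 ± 9.11 to 59.6 ± 1.99 CPM (log2 fold change -2.33, SE 0.07, edgeR adjusted p = 1.01e-12). TTC7A, which overlaps it on the opposite strand, rose by 0.71. The general transcription factor subunit GTF2A2 (chromosome 15, 59638062 to 59657541) fell by 2.12 on the log2 scale, and the ribosome biogenesis factor NSA2 (chromosome 5, 74766991 to 74780113) also fell by 2.12. MPP4 fell by 2.07 and the nucleosome-binding protein HMGN5 fell by 2.02. CEP55, which acts in the last step of cell division, fell 3.88-fold from 135 ± 6.94 to 34.8 ± 2.51 CPM. The sterol demethylase CYP51A1 fell by 1.82 and the phosphatase subunit PPP6R1 fell by 1.80. Of the 10 largest falls, 6 carried the 7-base word GAAGAGA or AAGAGAA in the 3' UTR, among them MCFD2, GTF2A2, NSA2, CYP51A1 and PPP6R1. CHAF1A, CEP55 and HMGN5 carried one elsewhere in the transcript, and MPP4 carried neither. Over all searched genes, 37.9% of 2799 lower genes had such a word in the 3' UTR, against 27.1% of 7045 genes that did not pass the test. These shares include the genes on which the words were chosen and are not adjusted for 3' UTR length or GC content.

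**Figure D2:**
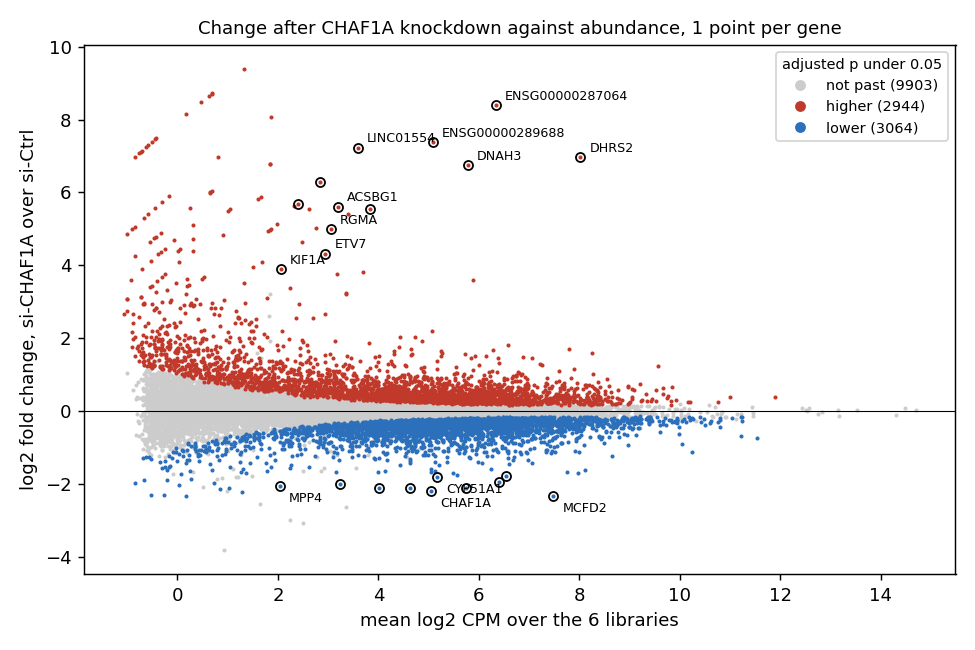
Log2 fold change of si-CHAF1A over si-Ctrl against mean log2 CPM for 15911 genes, with higher genes in red (2944), lower genes in blue (3064) and the rest in grey. Circles mark the genes named for the largest changes or smallest p-values. Among the circled genes, rises extend to 8.39 for ENSG00000287064 and falls to -2.33 for MCFD2.

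Of 44 tested mitosis genes, 42 were lower and 0 higher (42 and 1 adjusted over the list alone), with a median log2 fold change of -0.89 (camera adjusted p = 2.03e-20, and adjusted p = 0.114 with an estimated correlation). The mitotic kinase AURKA fell 2.74-fold, from 141 ± 4.39 to 51.5 ± 1.68 CPM, and PLK1 fell 2.42-fold, from 146 ± 10.7 to 60.4 ± 0.759 CPM. The spindle protein TPX2 fell 2.12-fold and the proliferation marker MKI67 fell 1.93-fold, from 658 ± 40.9 to 341 ± 16.1 CPM. The members not past the test were CDC25B (log2 fold change 0.16) and BIRC5 (0.00), both named after their values were seen. Of 46 DNA replication genes, 28 were lower and 1 higher (29 and 1 adjusted over the list alone), with a median of -0.30 (camera adjusted p = 4.03e-07, and adjusted p = 0.0701 with an estimated correlation). The ribonucleotide reductase subunit RRM1 fell by 0.72 on the log2 scale, DNA polymerase alpha's catalytic subunit POLA1 fell by 0.84, and the helicase factors MCM6 and MCM10 fell by 0.56 and 0.60. DNA damage repair genes were lower in 14 and higher in 1 of 30 (17 and 1 adjusted over the list alone, camera adjusted p = 0.000696, and adjusted p = 0.285 with an estimated correlation), with BARD1 fallen by 0.91.

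Of 13 tested replication-dependent histone genes 10 were higher and 0 lower (10 and 0 adjusted over the list alone), with a median log2 fold change of 1.54 (camera adjusted p = 1.48e-05, and adjusted p = 0.0701 with an estimated correlation). H2BC5 rose 5.90-fold, from 1.87 ± 0.247 to 11.01 ± 0.499 CPM, and the linker histone H1-2 rose 2.90-fold, from 3.87 ± 0.386 to 11.2 ± 1.65 CPM. The 3' UTR of H2BC5 held CGGAGAA or TCGGAGA, words more frequent in higher genes that the closing section describes. That of H2BC6 held a word more frequent in lower genes. H4C8 and H2BC6 rose by 2.42 and 2.82 on the log2 scale from levels under 1 CPM. Summed over all 61 listed histone genes, the level went from 48.4 ± 2.38 to 85.9 ± 4.51 CPM. Reads of near-identical copies can be split between members, so single histone genes are less certain than the sum. RNAs without a poly(A) tail summed to 86.2, 246 and 135 CPM in the control and to 135, 145 and 102 CPM in the knockdown libraries.

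Targets of the tumour suppressor p53 rose in 21 and fell in 3 of 32 (24 and 3 adjusted over the list alone), with a median log2 fold change of 0.39 (camera adjusted p = 1.48e-05, and adjusted p = 0.0701 with an estimated correlation). The pro-apoptotic BBC3 rose 2.03-fold, from 15.9 ± 1.28 to 32.3 ± 1.64 CPM, FDXR rose 1.79-fold, and TP53INP1 and SESN1 rose 1.64-fold and 1.61-fold. CDKN1A, the cell cycle inhibitor among these targets, was at a log2 fold change of -0.01 (edgeR adjusted p = 0.924; named after its value was seen). Genes of NF-kB and inflammatory cytokines rose in 14 and fell in 4 of 24 (15 and 4 adjusted over the list alone, median 0.55, camera adjusted p = 0.004, and adjusted p = 0.115 with an estimated correlation). SOD2, the mitochondrial superoxide dismutase, rose 2.35-fold from 455 ± 11.9 to 1069.95 ± 41.1 CPM. The chemokines CCL20, CXCL1 and CCL2 rose 2.83-fold, 3.14-fold and 3.64-fold.

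Interferon-stimulated genes did not pass the list test. Of these, 11 of 43 were higher and 4 lower (11 and 4 adjusted over the list alone), with a median of 0.17 (camera adjusted p = 0.0568, and adjusted p = 0.223 with an estimated correlation). Without si-CHAF1A 1 or si-CHAF1A 3, 2 were lower. Among the 11 members without any of the words of the siRNA scan 1 was higher and 1 lower, with a median of 0.04 (bootstrap 95% interval -0.11 to 0.19), against 10 higher and 3 lower of 32 with a word and a median of 0.27 (0.13 to 0.43). The words of lower and of higher genes are pooled here, so this difference does not point to either siRNA. OAS3 fell 1.81-fold, from 46.7 ± 2.57 to 25.8 ± 0.885 CPM, while TRIM22 and GBP2 rose 1.91-fold and 2.13-fold and BST2 rose from 0.261 ± 0.0601 to 2.00 ± 0.389 CPM. Sensors of nucleic acids were higher in 4 and lower in 2 of 16 (4 and 2 adjusted over the list alone, camera adjusted p = 0.616), with IFI16 up by 0.60 and STING1 by 1.11 on the log2 scale and IFIH1 at -0.67. For MHC class I antigen presentation, 6 of 12 were higher and 0 lower (6 and 1 adjusted over the list alone, camera adjusted p = 0.218), among them ERAP1 (0.56) and B2M (0.44).

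Genes derived from endogenous retroviruses and transposons were higher in 7 and lower in 0 of 18 (8 and 0 adjusted over the list alone, median 0.24, camera adjusted p = 0.00903, and adjusted p = 0.285 with an estimated correlation). The members that rose are mostly domesticated host genes: PGBD5 and PGBD1, descended from a DNA transposase, ARC, which forms capsid-like particles in neurons, and RTL8C, of retrotransposon Gag origin. PGBD5 rose 1.68-fold, from 31.1 ± 2.53 to 52.3 ± 3.13 CPM, and ARC rose 3.07-fold from 0.993 ± 0.296 CPM. The retroviral envelope genes ERV3-1 and ERVMER34-1 were at 0.23 and -0.09 and did not pass (named after their values were seen). Transposon silencing factors were higher in 4 and lower in 12 of 31 (4 and 13 adjusted over the list alone, camera adjusted p = 0.0641, and adjusted p = 0.256 with an estimated correlation). The higher members of this list came to 1 without si-Ctrl 1, si-Ctrl 3 or si-CHAF1A 1 and to 0 without si-CHAF1A 2 or si-CHAF1A 3, with 8 to 14 lower over the left-out libraries. Among the 7 members without any of the words of the siRNA scan 1 was higher and 2 lower, with a median of 0.01 (bootstrap 95% interval -0.17 to 0.13), against 3 higher and 10 lower of 24 with a word and a median of -0.18 (-0.26 to 0.01). CBX3 and CBX5, which bind methylated histone H3, fell by 0.82 and 0.42 on the log2 scale, the DNA methyltransferase DNMT1 fell by 0.51 and the histone methyltransferase SUV39H1 fell by 0.62. Early embryonic genome activation genes had 1 tested member, POU5F1 (0.24, not past the test). Cancer-testis genes had 3, TEX15 (-0.18), DDX43 (0.05) and PIWIL2 (0.07), none past the test. Clustered protocadherins were higher in 6 and lower in 1 of 35 (4 and 0 adjusted over the list alone, camera adjusted p = 0.151), with PCDHGB5 at 0.59.

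Genes of RNA acetylation and the nucleolar machinery around it were lower in 11 and higher in 0 of 15 (13 and 0 adjusted over the list alone, median -0.29, camera adjusted p = 0.00139, and adjusted p = 0.115 with an estimated correlation). Beside NAT10, the box C/D factors NOP56 and NOP58 fell by 0.39 and 0.34 and UTP15 fell by 0.49 on the log2 scale. Ribosomal proteins were lower in 32 and higher in 0 of 46 (37 and 0 adjusted over the list alone, median -0.26, camera adjusted p = 1.16e-06, and adjusted p = 0.362 with an estimated correlation), RPL27 by 1.65-fold. Leaving out 1 library moved the lower members to 7 for RNA acetylation (without si-CHAF1A 3) and to 20 for ribosomal proteins (without si-CHAF1A 2). MYC targets were lower in 20 and higher in 2 of 30 (21 and 3 adjusted over the list alone, camera adjusted p = 0.000205, and adjusted p = 0.268 with an estimated correlation). Among them RRS1 fell by 0.78 and NOLC1 rose 2.12-fold, from 125 ± 2.93 to 265 ± 7.83 CPM. Oxidative phosphorylation genes were lower in 16 and higher in 1 of 31 (18 and 2 adjusted over the list alone, camera adjusted p = 0.00324, and adjusted p = 0.285 with an estimated correlation), with NDUFB3 at -0.59 and UQCRB at -0.46. Mitochondrially encoded genes were higher in 1 and lower in 1 of 15 (1 and 1 adjusted over the list alone, camera adjusted p = 0.859), with MT-CO2 at -0.13 and MT-ND4 at -0.12, not past the test. Without si-Ctrl 2, 5 of them were higher.

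Cholesterol synthesis genes were lower in 15 and higher in 5 of 25 (15 and 5 adjusted over the list alone, median -0.35, camera adjusted p = 0.012, and adjusted p = 0.362 with an estimated correlation). Among them HSD17B7 fell 1.45-fold and FDPS 1.29-fold. CYP51A1 carried a GAAGAGA or AAGAGAA word in the 3' UTR. Among the 9 members without any of the words the median was -0.28 (bootstrap 95% interval -0.53 to 0.35), against -0.36 among the 16 with one, and with fewer members the list did not pass (camera adjusted p = 0.363). Glycolysis and hypoxia genes were higher in 6 and lower in 13 of 30 (6 and 13 adjusted over the list alone, camera adjusted p = 0.224), with EGLN3 and LDHA lower by 2.01-fold and 1.36-fold and PFKL higher by 1.82-fold. ATF4 and unfolded protein response genes were higher in 8 and lower in 8 of 29 (8 and 9 adjusted over the list alone, camera adjusted p = 0.711), and their median was 0.01 and their mean -0.07. Their higher members came to 5 without si-Ctrl 3 or si-CHAF1A 1 and their lower members to 5 without si-CHAF1A 1 or si-CHAF1A 2, and the higher cholesterol synthesis genes came to 3 without si-Ctrl 1, si-Ctrl 3 or si-CHAF1A 1. The serine synthesis enzyme PSAT1 fell 2.00-fold and TRIB3 rose 1.47-fold. Heat shock genes were lower in 6 and higher in 1 of 13 (6 and 1 adjusted over the list alone, camera adjusted p = 0.0568), led by HSP90AA1, which fell from 2959 ± 55.4 to 1827 ± 24.4 CPM.

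Cholangiocyte and epithelial markers were higher in 13 and lower in 4 of 20 (14 and 4 adjusted over the list alone, median 0.36, camera adjusted p = 0.004, and adjusted p = 0.285 with an estimated correlation). KRT19, a keratin of bile duct cells, rose 1.57-fold, from 716 ± 78.1 to 1123 ± 67.0 CPM, and ANXA4 and ELF3 rose 1.53-fold and 1.54-fold. Genes of mesenchymal transition and matrix were higher in 19 and lower in 6 of 35 (19 and 6 adjusted over the list alone, median 0.21, camera adjusted p = 0.00609, and adjusted p = 0.268 with an estimated correlation). Among the 7 members without any of the words the median was also 0.21 (bootstrap 95% interval 0.11 to 0.32), and with fewer members the list did not pass (camera adjusted p = 0.19). L1CAM rose 2.19-fold, THBS1 1.60-fold and COL5A1 1.78-fold. Of the fibroblast, endothelial and immune markers 7 were tested, with 3 higher and 0 lower (3 and 0 adjusted over the list alone, camera adjusted p = 0.00903, and adjusted p = 0.223 with an estimated correlation). These were ACTA2, from 6.19 ± 0.686 to 14.8 ± 0.915 CPM, PDGFRB, from 1.295 ± 0.133 to 5.37 ± 1.06 CPM, and VWF, from 0.627 ± 0.311 to 3.76 ± 1.21 CPM, all low in both groups. That call was lost without si-Ctrl 2 (camera adjusted p = 0.0677) and without si-CHAF1A 1 (0.0525), and 5 markers were higher without si-Ctrl 1. Hepatocyte markers were higher in 3 and lower in 1 of 9 (4 and 1 adjusted over the list alone, camera adjusted p = 0.289), with HNF4A at 0.33, and 1 was higher without si-Ctrl 1 or si-CHAF1A 1. Immediate early genes were higher in 7 and lower in 5 of 20 (7 and 6 adjusted over the list alone, camera adjusted p = 0.711), with FOSL1 down 1.68-fold and KLF2 up 2.20-fold. YAP and Notch targets were higher in 6 and lower in 4 of 21 (6 and 4 adjusted over the list alone, camera adjusted p = 0.973, direction down against a median of 0.02), with JAG1 at -0.64 and CCN2 at 0.73, and 8 were lower without si-Ctrl 2.

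**Figure D3:**
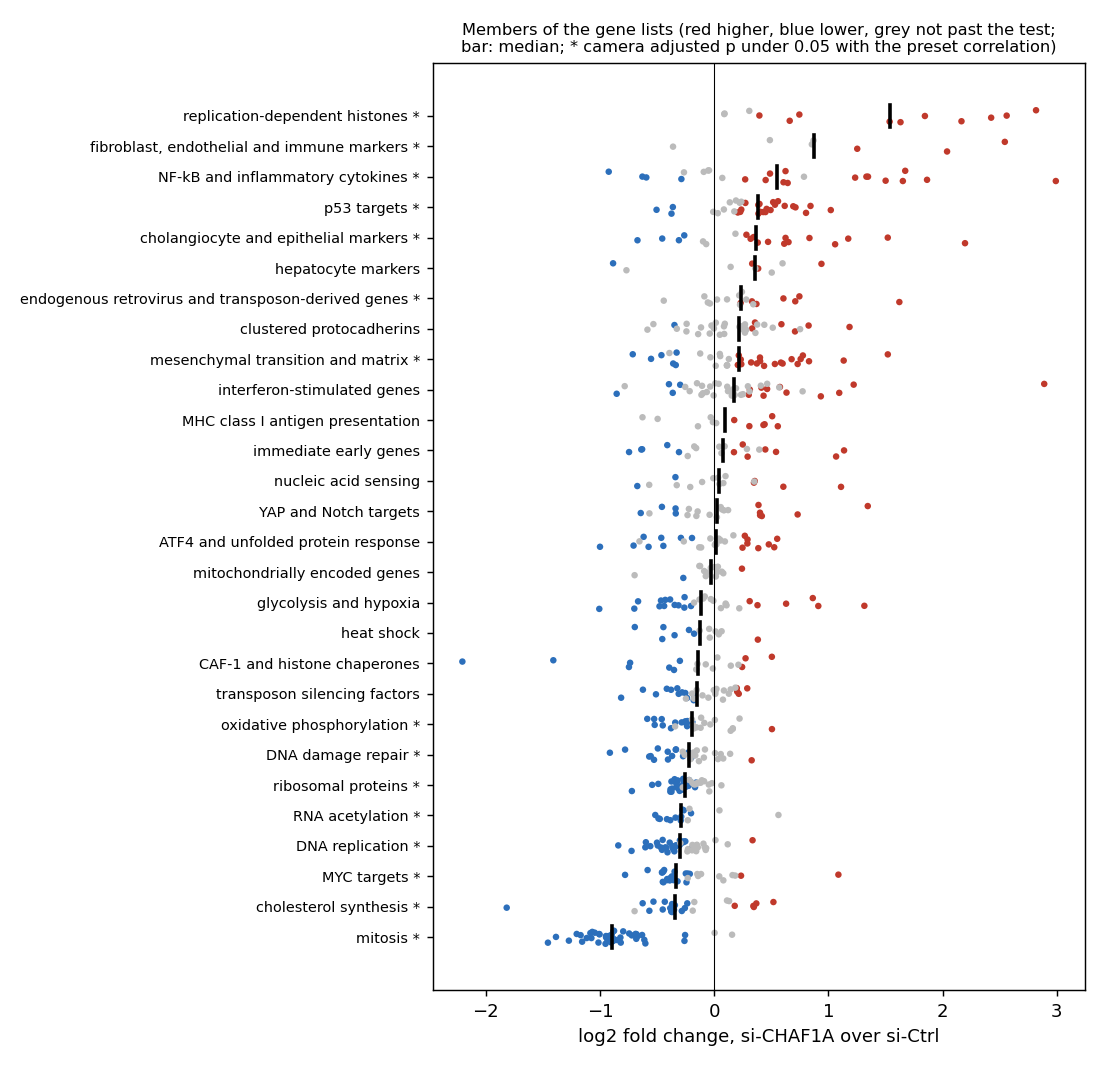
Log2 fold change of each tested member of the 28 gene lists with at least 5 tested members, with bars at the list medians. Red members were higher, blue lower and grey not past the test. Mitosis genes lie lowest (median -0.89) and replication-dependent histones highest (median 1.54).

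The share of changed genes that rose differed with abundance. Among protein-coding genes with a mean log2 CPM under 2, 485 were higher and 76 lower, against 2159 higher and 2811 lower at or over that level (odds ratio 8.30, 95% interval 6.46 to 10.8; Fisher's exact test across genes, two-sided, p = 2.02e-90). Long non-coding genes were higher in 207 and lower in 61, and processed pseudogenes in 14 and 82. Compared with protein-coding genes of the same low abundance, long non-coding genes showed no detected difference in that share (odds ratio 0.75, 95% interval 0.46 to 1.27; Fisher's exact test, two-sided, p = 0.248). Genes are not independent replicates in these tests.

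The list calls rest on the preset correlation: 7 lists were called higher and 8 lower of 28, and 0 with an estimated correlation (6 at an unadjusted p under 0.05 in camera, while fry called 23). Without si-Ctrl 2, the library that stood apart, 3519 genes were higher and 3709 lower, and mitosis, histone and p53 genes were 42 of 44 lower, 9 of 14 higher and 25 of 32 higher.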

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

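Each named gene past the test kept its direction in every alternative run for it. The CHAF1A log2 fold change kept its call in all of them and lay between -2.28 and -2.13 when 1 library was left out. Across other tools, scalings, filters and left-out libraries, the counts of higher and lower genes stayed within 1.5 times the reported ones, and no gene turned from one call to the opposite (0). Requiring a log2 fold change of at least 1 left 667 higher and 232 lower genes, and testing against a 1.2-fold change left 1525 and 1268. Restricting the test to genes without any of the words of the siRNA scan, an alternative added after seeing the data, left 929 and 754, with 4293 genes tested. The higher share of calls was 49.0% with TMM and at most 58.4% under another scaling, and the median of all genes moved to at most 0.05 on the log2 scale.

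The number of lists called was 0 with an estimated correlation and 23 with fry, which asks another question than camera. With the replicate block it was 16. No effect shared by same-numbered libraries was detected: their deviations correlated at -0.086, -0.064 and -0.003. The labels do not say whether same-numbered cultures were handled together. With the replicate block 2675 genes were higher and 2723 lower, and transposon silencing factors were higher in 0 and lower in 9.

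Directions turned only among results that did not pass the test. Leaving out 1 library moved POU5F1 between -0.0325 and 0.66, PIWIL2 between -0.15 and 0.26, MT-ND4 between -0.21 and 0.0105, and DDX43 between -0.11 and 0.19. YAP and Notch targets turned upward under fry (adjusted p = 0.926), with library totals only (0.967), for genes without the words (0.846), and for 1 left-out library (range of adjusted p 0.764 to 0.948). Mitochondrially encoded genes turned with library totals only (0.967) and when si-Ctrl 2 or si-CHAF1A 1 was left out (range 0.197 to 0.925), and ATF4 and unfolded protein response genes for genes without the words (0.67) and without si-Ctrl 2 (range 0.369 to 0.961). The causes were not tested. Depth limits the largest rises, since 3 of them rest on 8 to 10 control counts. Among genes named in the results, HNF4A lost its call without si-Ctrl 1, si-Ctrl 3 or si-CHAF1A 1 (adjusted p = 0.0643, 0.0534 and 0.105) and RBBP4 without si-CHAF1A 2 (0.0617), while TEX15 gained one without si-Ctrl 2 (0.009). Of lists just over the threshold, transposon silencing factors passed without si-Ctrl 2 (0.0441), heat shock genes without si-Ctrl 3 (0.0458), histone chaperones without si-CHAF1A 2 (0.0405) and with library totals only (0.0459), and interferon-stimulated genes with the replicate block (0.0487). These 4 lists also passed with no filter on low counts (0.00797, 0.0482, 0.0117 and 0.0482).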

Other observations

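Of the tests below, the one of the control siRNA words, the ones on background reads, scaling and histone genes, and the gene families were chosen only after the result was seen. The thinning used for depth was also added after the data were seen. Among 26 families defined by symbol stem, 9 of 11 CXC and CC chemokines were higher and 0 lower (camera adjusted p = 4.22e-06, and adjusted p = 0.151 with an estimated correlation). CXCL6, a neutrophil attractant, rose 6.31-fold, from 2.08 ± 0.227 to 13.1 ± 0.306 CPM (n = 3 each). Collagens were higher in 15 and lower in 2 of 25 (adjusted p = 0.151 with an estimated correlation). COL9A2 rose from 0.689 ± 0.150 to 5.98 ± 0.664 CPM and COL17A1 rose 1.84-fold, while COL13A1 fell by 0.60 on the log2 scale.

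Among families of basic cell machinery, none passed with an estimated correlation (adjusted p from 0.151 to 0.201). Mitochondrial ribosomal proteins were lower in 32 and higher in 2 of 76, with MRPL33 down 2.37-fold from 32.5 ± 1.19 to 13.7 ± 0.412 CPM. Proteasome subunits were lower in 21 and higher in 0 of 38 (median -0.26), among them PSMD1 and PSMA7 at 1.61-fold and 1.78-fold lower. Spliceosome proteins were lower in 18 and higher in 0 of 35, and centromere proteins in 14 and 1 of 21, with CENPE 2.01-fold lower.

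The lower genes carried a sequence signature. Genes whose 3' UTR held the word GAAGAGA had log2 fold changes shifted by -0.1945 in the held-out genes (95% interval -0.23 to -0.16), rank 1 of 16384 words, with 0 of 34 words of the same composition as extreme (a scan over all genes had been seen before). This word or its partner AAGAGAA was also in the 3' UTRs of OAS3, RRM1, EGLN3, PSAT1, CBX5 and UTP15, which fell. The 3' UTRs of ACSBG1, THBS1, TRIM22, PDGFRB, PGBD5 and HNF4A, which rose, held one too. CHAF1A's own transcript held the joined word GAAGAGAA, as do 20.3% of transcripts of similar length, so the values are consistent with seed pairing of the transfected siRNA, whose sequence is not in the labels. Genes whose 3' UTR held CGGAGAA had log2 fold changes higher by 0.1868 (0.11 to 0.26), rank 2 in that direction, which may reflect silencing by the control siRNA in control cells. This word or its partner TCGGAGA was in the 3' UTRs of H2BC5, NOLC1, ELF3 and BST2, which rose, and of SLC7A5, which fell. Of the 6 named largest rises with a coding transcript, 0 held either word in the 3' UTR. For DNAH3 and KIF1A the 3' UTR of the transcript searched was under 50 bp, and both held one of these words elsewhere in the transcript. The excess of word-bearing genes came to about 301 of 2799 lower genes (10.7%). This count includes the genes on which the words were chosen and is not adjusted for 3' UTR length or GC content. Mitosis genes without any of the 4 words still had a median of -1.008 (10 of 11 lower, bootstrap 95% interval -1.20 to -0.68). That argues against seed pairing through these 4 words as the source of the fall in those 11 transcripts. Pairing through other words, or in other transcripts of these genes, was not tested. An unrelated word also went with lower fold changes over all genes (shift over its standard error -7.39) and was not removed. An indirect effect through other silenced genes stays open, as does CHAF1A loss.

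The rise of low-abundance genes was weighed against background reads, scaling and depth, after the split under the reported scaling had been seen. Summed over 404 olfactory receptor genes, the level was 5.05 to 6.33 CPM in control and 7.19 to 7.29 CPM in knockdown libraries. The median gain per kb of 4077 low-abundance genes, whatever their call, was 26.11 times the gain per kb of those receptor genes (20.8 to 30.6 with 1 library left out), which argues against an even background such as genomic DNA. The gain less 5 times the receptor gain had a bootstrap 95% interval of 0.030 to 0.048 CPM per kb. The low-abundance genes had passed the count filter, which libraries of 1 group alone could satisfy. The receptor genes were not filtered. The median log2 fold change of all low-abundance genes tested lay 0.2004 above that of other genes (bootstrap 95% interval 0.18 to 0.22, and 0.19 to 0.21 with 1 library left out). A factor common to all genes of a library cannot make such a difference, so scaling alone does not account for it. Such a factor moves all genes together, so the difference does not show how far low-abundance genes rose by themselves. Their median was 0.16 as scaled, and that of other genes -0.04. The share of called low-abundance genes that rose was 80.6% as reported and 80.42% after thinning to the smallest total, so depth alone does not account for that share. An effect of CHAF1A loss and siRNA sequence effects both stay open.

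The higher level of histone genes was weighed against the assignment of reads and RNA without a poly(A) tail. Their summed level was 1.776-fold higher, above every control library in each knockdown library, so the splitting of counted reads between copies does not account for the sum. Whether reads that map to several copies were counted is not given. If they were left out, the sum could still depend on them. RNAs without a poly(A) tail had a log2 ratio of -0.2866 between the groups, but of 0.21 without si-Ctrl 2, which held 246 CPM of them against 86.2 and 135 in the other controls. The highest pair of libraries stood at 0.75, above a bound of 0.41 set from the log2 change of the histone sum (0.83). More such RNA in knockdown libraries therefore stays open, as do siRNA sequence effects and an effect of CHAF1A loss.

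Of the 10 ways to split the 6 samples into 3 and 3, only the real one gave as many genes (1 of 10, for higher and for lower genes alike): 2944 and 3064, against at most 1 in any other split. With 10 splits the share cannot fall under 0.05.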
